A study of Homo sapiens with 8 samples.

How the data were processed

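RNA-seq and Ribo-seq libraries of SH-SY5Y, an established human neuroblastoma cell line, were compared between cells carrying a short hairpin RNA against RPS29 and cells carrying a control hairpin. The series holds 8 libraries in 4 groups of 2. Each assay has 4 libraries, and RNA-seq and Ribo-seq were made as separate libraries. Per the labels' protocols, RNA-seq used total RNA and a stranded total RNA kit. For Ribo-seq, lysates made with cycloheximide were treated with RNase I and single ribosomes were taken by a size column. The protected fragments were depleted of rRNA and made into libraries with a small RNA kit.

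The deposited values are whole-number counts per gene symbol, in 1 table per assay, with no normalization seen in them. Per the submitters' processing notes, Trim Galore, Salmon, Bowtie2, STAR and featureCounts were used with build hg38. Which tool made which table, the versions, the annotation and the order of steps are not given in the sources used here. It is likewise not given whether Ribo-seq reads were limited to coding exons or to a footprint length, or cleared of rRNA, tRNA and other small RNA by mapping. This affects what a Ribo-seq count means: reads in introns, and reads of small RNAs encoded inside a gene, would be counted as footprints of that gene if counting ran over whole genes. Reads shared by overlapping genes or near-identical copies can be split or counted more than once, so such genes are uncertain. No gene of the mitochondrial genome is listed in the Ribo-seq table. Each row has a total of at least 3 counts in both tables.

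RNA-seq totals were 18125164 and 18539460 counts in the control libraries and 19156104 and 17539104 in the knockdown libraries, over 17927 genes. Ribo-seq totals were 2899655 and 3235621 in the controls and 2630463 and 4375971 in the knockdown, over 14019 genes. The tables share 12873 symbols. Symbols were matched to the RefSeq table of GRCh38.p14 for gene type, position and span, which gave 17693 of the 17927 RNA-seq symbols and 13956 of the 14019 Ribo-seq symbols.

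Differential expression was tested per gene on the counts with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the filterByExpr count filter, and Benjamini-Hochberg adjustment. Genes with an adjusted p below 0.05 were called. Standard errors of log2 fold changes were derived as the absolute log2 fold change divided by the square root of F. CPM values are counts scaled to a common library size with the TMM factors, except that RNA levels used to class or match genes, and Ribo-seq medians of those classes, are scaled to the total counts alone. Translational efficiency, the ratio of footprints to RNA, was tested as the assay-by-condition interaction in 1 edgeR model over all 8 libraries, with TMM factors computed within each assay and genes that passed the filter in both. That model has 1 dispersion per gene for both assays, although Ribo-seq varied more between replicates than RNA-seq. The median standard error was 0.575 there and 0.738 in Ribo-seq alone, although a change in the ratio also carries the RNA error. Standard errors of translational efficiency therefore understate the spread of footprints, and p-values resting on them need caution. In a simulation on the real means and library sizes with 200 changed genes, the RNA-seq test recovered 62.7% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 8 false calls among 14532 genes tested. The Ribo-seq test recovered 0 and 0% at 1.5-fold and 2-fold and 4.55% at 4-fold, and the translational efficiency test recovered 0% at each of the 3 sizes. Small and moderate footprint changes were therefore not detectable at this depth and spread.

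A total of 25 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. For each list the called members were counted, over all genes tested and adjusted over the list alone, and camera of limma 3.58.1 was run with a preset correlation of 0.01, on lists with at least 5 tested members, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. With so few libraries the estimated correlation is itself poorly determined. Named genes are RPS29, then up to 6 protein-coding genes with the largest called increase and 6 with the largest called decrease among those with at least 10 CPM in the higher group and both knockdown libraries on the same side of both controls (in translational efficiency, no overlap over any combination of libraries, with 10 CPM in both assays), then the 3 members of each list with the smallest p. Pseudogenes, unnamed loci and RNA genes were passed over, and list members were left out where space was short. Any other gene named was chosen after its values were seen.

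The alternatives were size factors (RLE) in place of TMM, DESeq2 1.42.0, limma-voom, no count filter, a filter of at least 50 counts in every group mean, the replicate number as a block, each library left out, and a test against a 1.5-fold change. For translational efficiency TMM over all libraries together and limma-voom with sample quality weights were added. After the data were seen, Ribo-seq and translational efficiency were also tested in 2 smaller sets of genes: those with a mean RNA CPM of at least 10, and, within these, low-background genes. A low-background gene holds no annotated snoRNA, miRNA or tRNA gene inside its span and has an expected background under 10% of its Ribo-seq count averaged over all 4 libraries, so that its change can affect whether it is included. The expected background is the median count per kb of genes with at most 0.1 RNA CPM, times the gene's span. Library sizes and TMM factors were computed anew within each of the 2 sets, so a gene's fold change differs from that of the full fit. Replicates of each group differed by more than sampling noise (chi-square per degree of freedom of 3.42 and 9.75 in RNA-seq, 34.0 and 84.1 in Ribo-seq), so none was treated as a repeat of another. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.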

Results

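The series measured RNA levels and ribosome-protected fragments after knockdown of RPS29, a protein of the small (40S) ribosomal subunit, in SH-SY5Y neuroblastoma cells. Each assay had 2 knockdown and 2 control libraries. RNA-seq libraries held between 17539104 and 19156104 counts and Ribo-seq libraries between 2630463 and 4375971. In RNA-seq the 4 genes with most counts took between 2.73 and 3.16% of a library. In Ribo-seq they took 45.9 and 51.6% in the controls and 35.3 and 52.3% in the knockdown, so the depth left for other genes was far lower. Spearman correlations between libraries, across genes, lay between 0.984 and 0.993 in RNA-seq and between 0.455 and 0.827 in Ribo-seq. Ribo-seq knockdown replicate 2 correlated more with control replicate 1 (0.743) than with knockdown replicate 1 (0.732), which stood apart from the controls (0.528 and 0.455). The background expected over all genes was 16.04 and 7.27% of the counts in the knockdown libraries and 3.38 and 1.71% in the controls. This takes background to grow with gene span. In tested genes under 1 RNA CPM, counts ranked with span in the knockdown libraries (Spearman rho = 0.484 and 0.322) but barely in the controls (0.074 and 0.061). Expected background in the controls is therefore rough.

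RPS29 lies on chromosome 14, positions 49570988 to 49598710 (GRCh38.p14). Its RNA was at 148.5 ± 16.4 CPM (SD, n = 2) in the controls and 6.99 ± 0.762 CPM (SD, n = 2) in the knockdown, from 2430 and 2872 counts against 147 and 117. The log2 fold change was -4.40 (SE 0.115, edgeR adjusted p = 6.32e-12). In Ribo-seq RPS29 was at 49.2 ± 14.3 CPM in the controls and 9.33 ± 3.27 CPM in the knockdown (SD, n = 2), from 199 and 129 counts against 28 and 28, a log2 fold change of -2.41 (SE 0.602, adjusted p = 0.0193). Over the span of RPS29 a background of 9.83 and 7.42 counts was expected in the knockdown libraries and 2.29 and 1.29 in the controls. The Ribo-seq call ended without control replicate 1 (adjusted p = 0.148), control replicate 2 (0.0798) or knockdown replicate 2 (0.0848), while the log2 fold change stayed between -2.79 and -2.12. Tested among low-background genes alone it was -1.63 and not called (adjusted p = 0.190). Its counts are the same there, and the fold change differs because scaling was computed within that set.

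**Figure D1:**
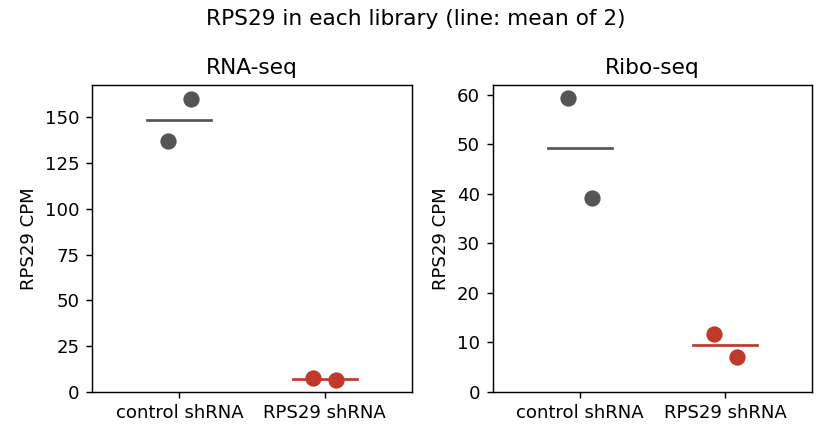
RPS29 in CPM (counts scaled to a common TMM-adjusted library size) in each RNA-seq library (left) and Ribo-seq library (right); points are libraries and lines are the means of 2. RNA-seq control libraries sit at 136.9 and 160.1 CPM and knockdown libraries at 7.53 and 6.46 CPM.

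The first comparison asked which RNAs differ between knockdown and control cells. Of 14723 genes tested, 2126 were higher and 2396 lower in the knockdown, of which 123 and 211 changed more than 2-fold. The RNA of CDKN1C, an inhibitor of cyclin-dependent kinases, fell (log2 fold change -2.19, SE 0.0974), as did WNT6 (-1.77), a secreted WNT ligand, TOX2 (-1.62) and H2AX (-1.59), a histone variant involved in the DNA damage response. Among the genes named by the rule, those that rose included DDIT3 (2.62, SE 0.194), a transcription factor of the stress response also known as CHOP, and IFRD1 (2.48, SE 0.0869). ZACN (1.92), a ligand-gated ion channel subunit, and ZFAND2A (1.65) rose too. RGPD6 (2.46) and RGPD5 (-2.03) moved in opposite directions, but they are near-identical copies whose reads can be split between them. DIP2C had 573 and 616 counts in the controls and 60 and 242 in the knockdown (-2.04). SNRNP25 rose by the named-gene rule (3.89), but this rests on a single library, with 16 and 13 counts in the controls and 24 and 421 in the knockdown. Without knockdown replicate 2 it was not called (0.60, adjusted p = 0.497), nor was it with limma-voom. SNRNP25, RGPD5, RGPD6 and DIP2C were not called with DESeq2. RGPD6 was at 4.20 without control replicate 1, RGPD5 at -3.21 without knockdown replicate 2, and DIP2C at -1.32 and -3.43 without knockdown replicate 1 and 2. Leaving out control replicate 1 reduced the calls to 1225 higher and 1517 lower and leaving out control replicate 2 to 1238 and 1496. Against a 1.5-fold change 69 genes were higher and 167 lower.

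Transcripts of the ribosome itself fell. Of the 31 other small-subunit protein genes, 23 were lower and 0 higher (25 lower adjusted over the list alone), with a median log2 fold change of -0.54. RPS9 was at -1.19 (SE 0.0794), RPS25 at -0.92 and RPS23 at -0.82. Of 47 large-subunit protein genes, 40 were lower and 0 higher (40 adjusted over the list alone), with a median of -0.50, and RPL23A (-0.94) and RPL37 (-0.92) had the smallest p. Among 25 translation factors and other genes with 5' terminal oligopyrimidine (TOP) mRNAs, 14 fell and 3 rose (16 and 3 adjusted over the list alone). EIF4B (-1.25) and EIF3L (-0.96), initiation factors, and TPT1 (-1.14) led the decreases. Camera called all 3 lists lower (adjusted p = 3.30e-15, 6.57e-23 and 6.44e-08), but with an estimated correlation each had an adjusted p = 0.456. TOP genes lower numbered 9 without either control replicate, and TOP genes higher 1 without control replicate 2. Against a 1.5-fold change the 3 counts were 2, 2 and 3.

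Genes that build ribosomes moved the other way. Of 49 ribosome biogenesis genes, 23 rose and 0 fell (29 and 3 adjusted over the list alone), with a median log2 fold change of 0.22, and RRP9 (1.09, SE 0.0935), UTP4 (0.76) and RRP12 (0.66), factors of small-subunit rRNA processing, were the clearest. Of 78 mitochondrial ribosomal protein genes, 26 rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 0.18. MRPL58 (0.65), MRPL38 (0.56) and MRPS10 (0.52) had the smallest p, and the median was 0.07 without knockdown replicate 1 and 0.28 without knockdown replicate 2. Camera called both lists higher (adjusted p = 1.44e-07 and 1.15e-05), with an adjusted p = 0.456 and 0.692 under an estimated correlation. The ribosome biogenesis count was 12 without control replicate 1 and 13 without control replicate 2, and the mitochondrial count was 51 without knockdown replicate 2. Mitochondrial ribosomal protein genes lower numbered 0 without control replicate 2 and 4 without knockdown replicate 1. Against a 1.5-fold change the counts were 1 and 0.

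Targets of p53 rose and cell-cycle genes fell. Of 38 p53 target genes, 23 rose and 4 fell (25 and 4 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 1.50e-10). GDF15, a secreted stress cytokine, was at 1.63 (SE 0.0921), CDKN1A, the cell-cycle inhibitor p21, at 1.41 (SE 0.0885) and PHLDA3 at 1.06. MDM2, the p53 ubiquitin ligase and a target itself, was at 0.01 (adjusted p = 0.933) and is named after its value was seen. Of 40 G2/M and mitosis genes, 39 fell and 0 rose (39 adjusted over the list alone), with a median of -0.64 (camera adjusted p = 2.00e-37). MKI67, the proliferation marker, was at -1.13, the spindle gene ASPM at -1.06 and CCNB1, cyclin B1, at -1.05. Of 39 G1/S and replication genes, 14 fell and 4 rose (15 and 4 adjusted over the list alone), with MCM6 at -0.70 and MCM2 at -0.64 (camera adjusted p = 0.00660). Replication-dependent histones had 5 of 22 genes lower and 0 higher (5 adjusted over the list alone), a list that camera did not call (adjusted p = 0.0540). With an estimated correlation, the p53 and G2/M lists had an adjusted p = 0.456 and the G1/S list an adjusted p = 0.605. G1/S genes lower numbered 8 and 9 without control replicate 1 and 2, and those higher 1 and 2. Against a 1.5-fold change, 5 p53 targets were higher and 7 G2/M genes lower.

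Of 24 cholesterol synthesis and uptake genes, 20 fell and 0 rose (20 adjusted over the list alone), with a median of -0.55, and INSIG1, a regulator of sterol synthesis, was at -1.41 (SE 0.105). Of 31 hypoxia and glycolysis genes 13 fell and 0 rose (14 lower adjusted over the list alone), led by VEGFA (-1.43), PDK1 (-1.33) and ALDOC (-0.91). Of 23 endoplasmic reticulum chaperone and unfolded protein response genes 8 fell and 0 rose (9 and 1 adjusted over the list alone), among them HSPA5 (-0.62), the chaperone BiP. Of 18 heat shock genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), with HSPA8 at -0.53. HSPA1A (-0.92) and HSPA1B (-0.66) are near-identical copies. Of 18 immediate early genes 8 rose and 2 fell (8 and 2 adjusted over the list alone), with EGR1 at 1.44 (SE 0.151), IER3 at 1.25 and JUNB at 0.71. Camera called these lists (adjusted p = 3.61e-16, 6.93e-05, 0.00486, 8.27e-04 and 7.43e-04 in that order), and with an estimated correlation each had an adjusted p = 0.456. Targets of ATF4 went both ways, with 7 of 37 higher and 6 lower (7 and 6 adjusted over the list alone), so that DDIT3 rose while DDIT4 fell (-0.97), and the list was not called (adjusted p = 0.481). Without control replicate 1 the hypoxia, unfolded protein response and heat shock lists had 8, 4 and 5 genes lower, and without control replicate 2 they had 8, 5 and 4. ATF4 targets lower numbered 3 without control replicate 2. Heat shock genes higher numbered 0 without control replicate 1 or knockdown replicate 1 and 3 without knockdown replicate 2, and immediate early genes lower 0 without control replicate 2 and 4 without knockdown replicate 1.

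Among cell identity lists, 14 of 32 neuronal differentiation genes fell and 3 rose (15 and 5 adjusted over the list alone), with STMN2, a growth-associated microtubule regulator, at -1.04 (SE 0.0732), TUBB3 at -0.94 and ELAVL3 at -0.92 (camera adjusted p = 9.59e-05, and adjusted p = 0.456 with an estimated correlation). Noradrenergic neuroblastoma genes went both ways, with 7 of 27 higher and 8 lower (8 and 11 adjusted over the list alone). TBX2 was at 1.07 and TFAP2B at -0.54. Mesenchymal genes likewise had 9 of 32 higher and 6 lower (11 and 7 adjusted over the list alone), with FOSL1 at 1.46, ACTA2 at 0.77 and SPARC at -0.55. Camera called neither list (adjusted p = 0.844 and 0.5). Without control replicate 1, noradrenergic genes lower numbered 5 and mesenchymal genes higher 4, and without control replicate 2 noradrenergic genes lower numbered 5. Neuronal genes higher numbered 1 without either control replicate and 5 without knockdown replicate 2. Markers of other cell types were scarce: of 17 epithelial markers 9 were tested and 2 were lower (2 adjusted over the list alone), CD24 (-0.53) and CDH1, the latter with 11 and 20 counts in the controls against 2 and 1. Of 15 blood cell markers 4 were tested, with CD68 (0.77) and CD14 (1.37) higher and CORO1A (-0.72) lower (2 and 2 adjusted over the list alone). CD14 had at most 27 counts in a library and was not called without any single library, and CD68 was not called without knockdown replicate 2 (0.50), so blood cell markers higher numbered 0 there and 1 without each other library. Epithelial markers lower numbered 1 without control replicate 2.

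Nuclear respiratory chain genes had 14 of 76 higher and 5 lower (10 and 5 adjusted over the list alone), with NDUFB9 at 0.65 and NDUFS5 at -0.80, and proteasome genes 8 of 31 higher and 3 lower (8 and 3 adjusted over the list alone), with PSMC5 at 0.57 and PSMD1 at -0.50. Mitochondrially encoded genes had 5 of 13 higher and 0 lower (5 adjusted over the list alone), with MT-ND6 at 0.57, MT-ND1 at 0.55 and a median of 0.26. These were at 0.35, 0.33 and -0.02 without knockdown replicate 2, and the median was 0.14 without control replicate 2 and 0.49 without knockdown replicate 1. Knockdown replicate 2 had 3.91% of its counts in all genes of the mitochondrial genome, the rRNA gene MT-RNR2 included. The other libraries had 2.15 to 2.87%. NRF2 and antioxidant genes had 10 of 24 lower and 2 higher (10 and 2 adjusted over the list alone), with TXNRD1 at -0.63. Interferon-stimulated genes had 5 of 35 higher and 3 lower (4 and 3 adjusted over the list alone), with OAS1 at -0.79. Of these lists camera called the mitochondrially encoded genes alone (adjusted p = 0.0109, and adjusted p = 0.692 with an estimated correlation). These counts depended on single libraries: respiratory chain genes higher numbered 5 without either control replicate, 9 without knockdown replicate 1 and 32 without knockdown replicate 2, and those lower 3, 1, 13 and 3 without control replicate 1 and 2 and knockdown replicate 1 and 2. Proteasome genes higher numbered 1 and 5 without control replicate 1 and 2 and 19 without knockdown replicate 2, and those lower 1 without either control replicate and 6 without knockdown replicate 1. Mitochondrially encoded genes higher numbered 2 without control replicate 2 and 13 without knockdown replicate 1, and without either control replicate antioxidant genes lower numbered 4 and higher 1. Interferon-stimulated genes higher numbered 3 without control replicate 2 or knockdown replicate 1.

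**Figure D2:**
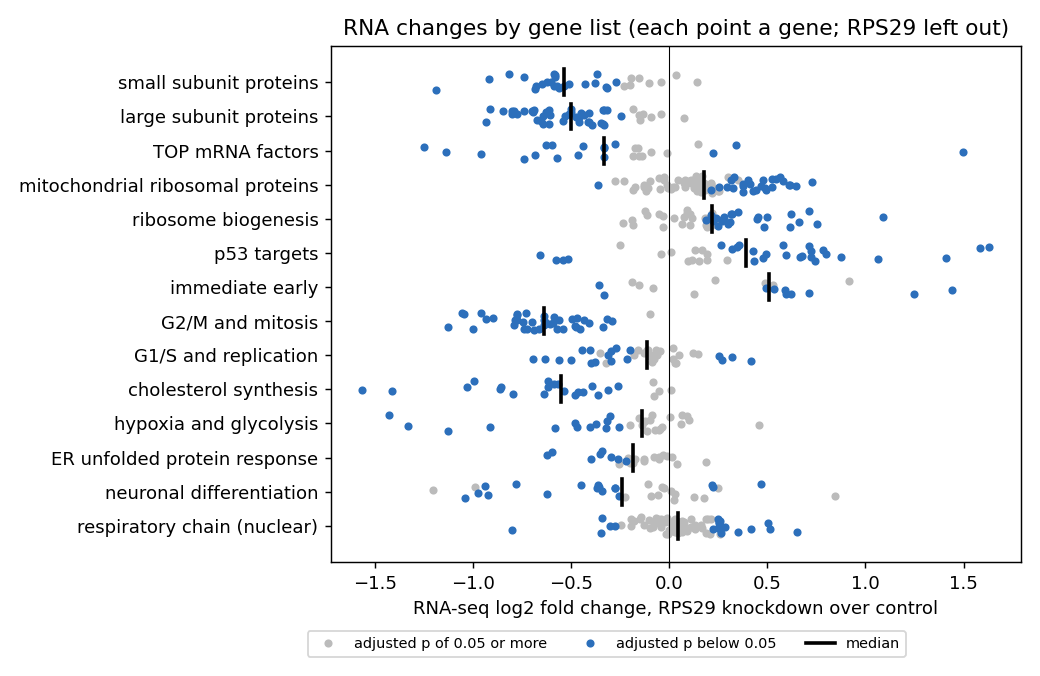
RNA-seq log2 fold change (knockdown over control) of the tested members of 14 gene lists; each point is a gene, blue where its adjusted p is below 0.05, and bars are medians. Ribosomal protein lists lie left of 0 with medians of -0.54 and -0.50 and p53 targets right of it with a median of 0.39.

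The second comparison asked where ribosome footprints differ. Footprints of CDKN1C fell as its RNA did, from 97 and 82 counts in the controls to 2 and 15 (log2 fold change -3.44, SE 0.771), and those of cyclin B1 (CCNB1, -2.44), the mitotic kinesin KIF2C (-2.25) and the kinase CDK1 (-2.42) fell too. RRM2, a subunit of ribonucleotide reductase, was at -1.92. In all, 944 of 11853 genes were higher and 72 lower. Genes with the largest increases had almost no control counts: ZFAT, a zinc finger gene, had 7 and 4 in the controls and 6085 and 2781 in the knockdown, HERC6 4 and 4 against 3708 and 2142, DPF1 8 and 17 against 11392 and 4894, NHERF2 2 and 6 against 3576 and 1410, BIK 1 and 0 against 410 and 243, and EPHA5, which is not listed in the RNA-seq table, 14 and 3 against 4724 and 2273. The largest decreases were those of CFAP299, also not listed in the RNA-seq table, with 16121 and 7107 counts against 105 and 89, and PARD3, a cell polarity gene, with 14724 and 31987 against 757 and 687. PHF13 (-3.90), RTL10 (-3.02) and PPDPF (-2.97) followed. Without control replicate 1 and 2 the calls were 694 and 20, and 268 and 5. Without knockdown replicate 1 and 2 they were 247 and 21, and 598 and 53. With at least 50 counts in every group mean they were 170 and 12. The calls of KIF2C, CDK1, RRM2 and PHF13 ended without any single library, that of CCNB1 without either control replicate, those of CDKN1C without knockdown replicate 1 and PARD3 without knockdown replicate 2, that of PPDPF without control replicate 1 or knockdown replicate 2, and that of RTL10 without any library but control replicate 1.

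The genes called higher in Ribo-seq differed from the rest in RNA level. Of these 944, 438 (46.4%) had a mean RNA CPM under 1, against 12.2% of all tested genes, and their median span was 186 kb against 42.7 kb. Genes with at most 0.1 RNA CPM had median Ribo-seq values of 2.07 and 0.93 CPM in the controls and 9.50 and 4.57 CPM in the knockdown, while genes over 100 RNA CPM had 35.5 and 34.6 against 16.7 and 23.1. Genes that hold a snoRNA, miRNA or tRNA gene took 54.9 and 54.9% of the counts in the controls and 47.3 and 65.8% in the knockdown, although they were 10.2% of the genes. Limited to 3066 low-background genes, 65 were higher and 2 lower, of which 54 and 2 were also called over all genes. The background share is taken over the mean of all libraries, so a rise in the knockdown can itself bring a gene into this set. NHERF2 would be out on the control libraries alone, with an expected background of 19.5% of its control counts, and is 1 of 22 such genes among the 3043 of the set that were tested over all genes.

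**Figure D3:**
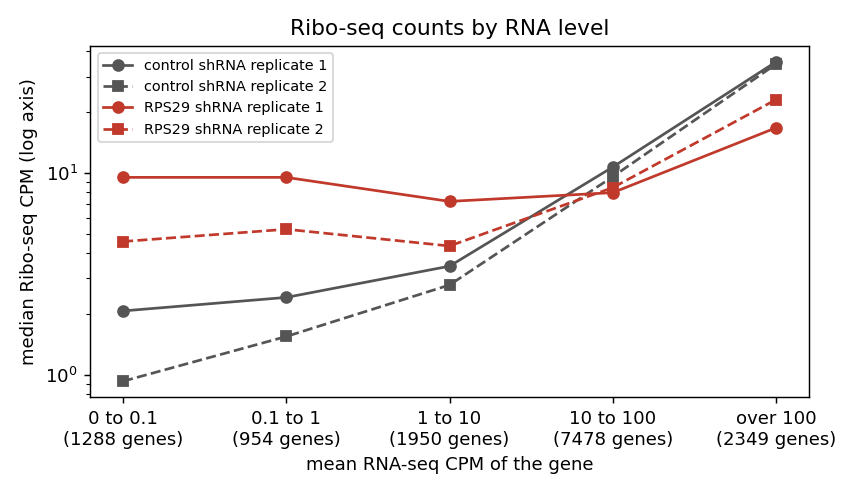
Median Ribo-seq CPM (scaled to total counts, log axis) of genes grouped by their mean RNA-seq CPM, for each of the 4 Ribo-seq libraries. In the group with at most 0.1 RNA CPM the knockdown libraries lie at 9.50 and 4.57 and the controls at 2.07 and 0.93, and in the group over 100 the order is the opposite.

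Among the lists, G2/M and mitosis genes had 6 of 39 lower and 0 higher (9 adjusted over the list alone) and a median of -1.36. Nuclear respiratory chain genes had 2 of 75 lower (0 adjusted over the list alone) and a median of -1.05. Cholesterol genes had 3 of 21 lower and 1, MSMO1 (4.46), higher (4 and 1 adjusted over the list alone), and G1/S genes 2 of 37 lower (4 adjusted over the list alone). The small-subunit proteins had 0 of 30 called, with a median of -0.51, and the large-subunit proteins 1 of 44, RPL35A (-2.32), with a median of -0.47 (0 and 0 adjusted over the list alone). These medians were -0.24 and -0.18 without knockdown replicate 1 and -0.79 and -0.97 without knockdown replicate 2, and that of the small subunit -0.80 and -0.25 without control replicate 1 and 2. Of 37 p53 targets 1, SESN1 (3.17), was called, higher (1 adjusted over the list alone). Of the other lists, neuronal genes had 4 of 32 higher and 1 lower and mesenchymal genes 2 of 31 higher. The interferon list had 1 of 15 higher and the immediate early list 1 of 13. Antioxidant, heat shock and epithelial genes each had 1 higher and 1 lower, of 19, 17 and 5. TOP factors, ATF4 targets, noradrenergic genes and proteasome genes each had 1 lower, of 22, 28, 25 and 31. The mitochondrial ribosomal, ribosome biogenesis, unfolded protein response, histone, hypoxia and blood cell lists had 0 called genes of 73, 49, 22, 50, 30 and 6. Over all lists 13 members were higher and 22 lower, and of these 7 and 1 kept their call without control replicate 1, 1 and 0 without control replicate 2, 8 and 4 without knockdown replicate 1, and 9 and 3 without knockdown replicate 2. G2/M genes lower numbered 0, 0, 1 and 3 in these fits and respiratory chain genes lower 0 in each. The call of SESN1 ended without any library but knockdown replicate 2 and that of RPL35A without either control replicate. Camera called 16 of 24 lists lower and 0 higher, with the lowest adjusted p for the respiratory chain and G2/M lists (2.07e-09 for both), and with an estimated correlation 0 lists were called (lowest adjusted p = 0.471). A median below 0 was found in 20 of the 24 lists. Over all genes, lower list calls therefore cannot be told apart from the lower Ribo-seq values of genes with much RNA described above. In the low-background genes the call of the G2/M list alone remained, with a median of -0.82 over 19 genes (adjusted p = 9.26e-05, and adjusted p = 0.788 with an estimated correlation). The medians of the ribosomal protein lists turned to 0.15 and 0.24 there. Scaling was computed anew in that set and fewer members were tested (19 and 22), so this turn cannot be laid to background.

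The third comparison asked whether footprints changed relative to RNA. Translational efficiency was called higher for 321 of 10648 genes and lower for 93. The named increases were ZFAT (log2 change 10.21, SE 0.954, adjusted p = 0.0249), DPF1, NHERF2, CLVS2 (7.03), XXYLT1 (237 and 114 control footprint counts against 20317 and 9457) and ODF2L (6.93), and 246 of the 321 were also called higher in Ribo-seq itself. The named decreases were PARD3 (-4.83, SE 0.641, adjusted p = 0.0289), PHF13 (-3.35), ARL16 (-3.15), CHST14 (-3.02), FKBP9 (-2.84) and GTF2A2 (-2.76). Of the 93 genes called lower, 21 were also called lower in Ribo-seq itself. RPS29 was at 2.09 (SE 0.481, adjusted p = 0.0535), since its footprints fell less than its RNA. That SE lies below the 0.602 of its footprint change alone and is therefore too small. Without any 1 of the 4 RNA-seq libraries, or without Ribo-seq control replicate 2, edgeR called 0 genes in either direction, with between 1491 and 3353 genes at an unadjusted p below 0.05. Without Ribo-seq control replicate 1 it called 971 higher and 500 lower, without knockdown replicate 1 756 and 563, and without knockdown replicate 2 2030 and 1712, and these 3 fits kept 288 to 320 of the 321 and 91 to 93 of the 93. A lone Ribo-seq library adds no spread of its own, and the dispersion is shared with RNA-seq. Calls kept in those 3 fits are therefore no sign of stability. The fold change of ZFAT stayed between 8.95 and 10.86 and that of PARD3 between -5.37 and -4.20 over the 8 fits without a library. CLVS2 reached 11.77 without Ribo-seq control replicate 1. DESeq2 on all libraries called 1015 and 675, and limma-voom 495 and 180.

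In translational efficiency, nuclear respiratory chain genes had 4 of 75 lower and 0 higher (15 adjusted over the list alone) and a median of -0.91, with COX7B at -3.38, ATP5MC1 at -2.12 and CYC1 at -2.04. Proteasome genes had 2 of 31 lower (3 adjusted over the list alone) with PSMD12 and PSMA4 (-1.95), and mitochondrial ribosomal protein genes 2 of 73 lower (2 adjusted over the list alone), MRPL34 (-2.32) and MRPL17 (-1.92). Ribosome biogenesis genes had 0 of 49 called and a median of -0.77, which was -0.47 without Ribo-seq control replicate 2. Camera called 9 of 22 lists lower, these 4 among them (adjusted p = 2.96e-09, 2.81e-05, 7.42e-05 and 1.98e-05 in that order), and with an estimated correlation 0 lists were called (lowest adjusted p = 0.409). A median below 0 was found in 17 of the 22 lists, so a lower median does not set a list apart here. Small-subunit and large-subunit protein genes had medians of 0.15 and 0.07 (-0.06 and -0.30 without Ribo-seq knockdown replicate 2, 0.36 and 0.31 without Ribo-seq knockdown replicate 1) and were not called (adjusted p = 0.940 for both), with 0 of 30 and 1 of 44 genes called, RPL6 (2.06, higher). Of the other lists, heat shock genes had 2 of 17 higher, neuronal genes 1 of 31 higher and 1 lower, and the p53, noradrenergic, cholesterol, interferon and antioxidant lists 1 higher each, of 37, 25, 21, 15 and 19. ATF4 targets, G1/S genes and epithelial markers had 1 lower each, of 28, 37 and 2. TOP factors, unfolded protein response, G2/M, histone, mesenchymal, hypoxia, immediate early and blood cell genes had 0 called, of 22, 22, 39, 20, 28, 29, 12 and 2. Over all lists 9 members were higher and 12 lower, against 0 without any 1 of the RNA-seq libraries or Ribo-seq control replicate 2, 28 and 60 without Ribo-seq control replicate 1, 36 and 88 without knockdown replicate 1, and 48 and 231 without knockdown replicate 2. In these last 3 fits respiratory chain genes lower numbered 13, 13 and 36, proteasome genes 2, 6 and 17, mitochondrial ribosomal protein genes 8, 10 and 26 and ribosome biogenesis genes 8, 10 and 22, and large-subunit genes higher 1, 7 and 2. In the low-background genes 2 genes were called higher, HSPA2 (named after its values were seen) and DPF1, whose expected background was close to the limit in the controls (9.63% of its counts), and 0 lower, and none of those 4 lists was called. There the small-subunit and large-subunit lists were called higher by camera (medians 0.77 and 0.57, adjusted p = 0.00216 for both, and adjusted p = 0.726 with an estimated correlation). These medians rest on the scaling of that set.

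Across genes, which are not independent replicates, RNA-seq and Ribo-seq fold changes were almost unrelated, with Pearson r = 0.028 and Spearman rho = 0.062 over 10648 genes. In the low-background genes r was 0.173 and rho 0.219, and rho was 0.326 over those of them called in RNA-seq, whose median Ribo-seq log2 fold change was 0.25 where RNA rose and -0.25 where it fell. Over all genes these medians were -0.12 and -0.35. With at least 10 RNA CPM they were 0.12 and -0.14. Genes not called in RNA-seq had medians of 0.01 over all genes, 0.08 with at least 10 RNA CPM and -0.01 in low-background genes. Scaling was computed within each set, so the sign of such a median depends on the set. In each set the median was higher where RNA rose than where it fell. Of genes called in both assays 49 were higher in both, where independent lists would share 92.2, and 37 lower in both, where 13.9 would be shared. In genes with at least 10 RNA CPM 53 were higher in both against 61.7, and 16 lower against 5.83, and in low-background genes 11 against 14.2, and 1 against 0.408. The sign of the correlation over all genes turned without RNA-seq knockdown replicate 2 (-0.026) and without Ribo-seq knockdown replicate 2 (-0.00049).

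**Figure D4:**
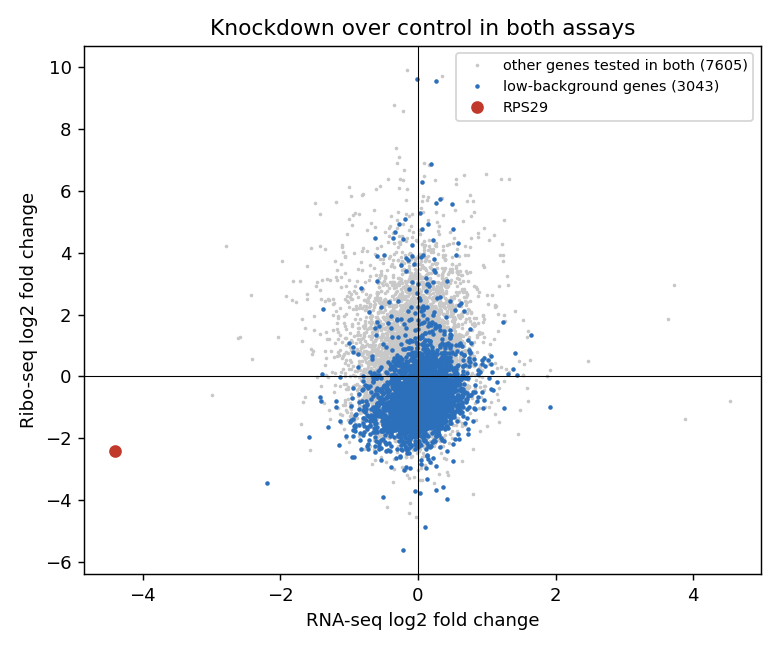
RNA-seq against Ribo-seq log2 fold change (knockdown over control) of genes tested in both assays; blue points are low-background genes, grey points other genes and the red point RPS29. RPS29 lies at -4.40 and -2.41, and Ribo-seq values spread up to 9.90 where RNA-seq values are near 0.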

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

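The 2 smaller gene sets were chosen after the data were seen, and the other alternatives before. RNA-seq calls kept their number within 1.5 times under RLE, DESeq2, limma-voom, both filters and the replicate block. Against a 1.5-fold change, RNA-seq counts were 69 higher and 167 lower, since small changes no longer pass, and list counts were 2 small-subunit, 2 large-subunit, 3 TOP, 7 G2/M, 6 cholesterol, 4 neuronal and 4 hypoxia genes lower, and 1 ribosome biogenesis, 0 mitochondrial ribosomal, 5 p53 and 2 immediate early genes higher. With an estimated correlation camera called 0 lists in every comparison, in place of 5 higher and 10 lower (RNA-seq), 16 lower (Ribo-seq) and 9 lower (translational efficiency). Fry called 1 higher and 5 lower in RNA-seq, without the small-subunit (adjusted p = 0.107), large-subunit (0.106), TOP (0.0876), ribosome biogenesis (0.0876), mitochondrial ribosomal (0.241) and p53 lists (0.0850), 0 in Ribo-seq and 7 lower in translational efficiency, where the mitochondrial ribosomal (adjusted p = 0.0593) and ribosome biogenesis lists (0.0869) were not called.

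Ribo-seq calls were less stable. Genes lower numbered 165 with DESeq2, 171 with limma-voom and 30 against a 1.5-fold change. With at least 50 counts in every group mean, 170 were higher and 12 lower, and with fewer genes tested the count falls by construction. In genes with at least 10 RNA CPM, 339 were higher and 27 lower, and in low-background genes 65 and 2, where RPS29 was at -1.63 (adjusted p = 0.190). Translational efficiency calls were 1015 higher and 675 lower with DESeq2, 495 and 180 with limma-voom, 44 and 29 with at least 50 counts, 146 and 16 against a 1.5-fold change, 173 and 50 with at least 10 RNA CPM, and 2 and 0 in low-background genes, with 613 at an unadjusted p below 0.05 there. Genes lower numbered 58 with no count filter. RPS29 passed the threshold for translational efficiency with DESeq2 (2.09, adjusted p = 0.00383) and limma-voom (2.07, adjusted p = 0.0497). The correlation of fold changes was 0.051 with at least 50 counts, 0.069 with at least 10 RNA CPM and 0.173 in low-background genes. Where no cause is given, the cause was not tested.

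Leaving out 1 library leaves a group with a lone sample, assumed to vary like the others. RNA-seq genes higher ranged from 1225 to 2739 and lower from 1496 to 2876, TOP genes lower from 9 to 20, ribosome biogenesis genes higher from 12 to 34, mitochondrial ribosomal genes higher from 18 to 51 and hypoxia genes lower from 8 to 14. Ribo-seq genes higher ranged from 247 to 694 and lower from 5 to 53, and RPS29 there from -2.79 to -2.12. Translational efficiency genes higher ranged from 0 to 2030 and lower from 0 to 1712, and RPS29 from 1.67 to 2.45. The correlation ranged from -0.026 to 0.061 and turned negative without RNA-seq knockdown replicate 2 (-0.026) or Ribo-seq knockdown replicate 2 (-0.00049). MDM2, never called, turned to -0.04 without RNA-seq control replicate 2 (-0.042) and without knockdown replicate 2, and reached 0.065 (0.0654) without control replicate 1. Of the named genes' values under alternatives, 986 of 1057 in RNA-seq, 315 of 461 in Ribo-seq and 302 of 566 in translational efficiency kept direction and call, and 69, 146 and 264 kept direction alone.

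The replicate numbers are shared between groups, but nothing in the labels pairs them. Same-numbered libraries deviated together with r = -0.11 in RNA-seq and 0.12 in Ribo-seq across genes. With the replicate block, RNA-seq calls were 1764 higher and 2048 lower, Ribo-seq calls 1402 and 397, and translational efficiency calls 22 and 0 (edgeR, 2948 at an unadjusted p below 0.05). By camera the block added the histone list in RNA-seq (adjusted p = 0.0323) and left out the ATF4 list in translational efficiency (0.0786, without the block 0.0464).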

Other observations

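All lists of this paragraph and the next were assembled after the data were seen, so the tests on them are exploratory, and only the bound for the decay factors was written before their values were looked at. Tubulin RNAs fell together, with 9 of 12 genes lower and 0 higher and a median log2 fold change of -0.67 (fry adjusted p = 0.0315, camera adjusted p = 1.02e-09, and adjusted p = 0.338 with an estimated correlation). They include the abundant TUBB (-0.71) and TUBA1B (-0.62). RNAs of secreted neuropeptides and granins went up in part: 5 of 11 rose and 1 fell, with VIP, vasoactive intestinal peptide, at 1.38 (SE 0.0849), VGF at 1.15 and SCG2 at 1.04 (camera adjusted p = 2.84e-06, and adjusted p = 0.338 with an estimated correlation). Their translational efficiency went the other way, with 2 of 11 lower, 0 higher and a median of -0.96 (camera adjusted p = 0.00200, and adjusted p = 0.315 with an estimated correlation). Their footprints had a median of -0.18 over 13 genes and were not called (camera adjusted p = 0.268). RNA is part of that ratio, so a list picked after the data were seen can be lower through its RNA alone. Of the 22 lists fixed beforehand and tested there, 17 had a median below 0 too. Elongation factors EEF1A1 (-0.60) and EEF2 (-0.44) fell as the ribosomal protein RNAs did (both named after their values were seen), but EEF2 was not called without either control replicate.

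Of 20 noncoding hosts of snoRNAs, 8 rose and 3 fell, with a median log2 fold change of 0.21 (camera adjusted p = 0.0192, adjusted p = 0.409 with an estimated correlation, and fry adjusted p = 0.130). SNHG1 was at 1.498 and SNHG7 at 1.45, while SNHG5 was at -1.41. Less nonsense-mediated decay is a candidate explanation for the rise of SNHG1, SNHG7 and IFRD1. RNAs of decay factors that this pathway itself degrades had a median log2 fold change of 0.026 over 8 genes, with 2 higher, under the bound of 0.1 set for no loss of decay. By the rule written beforehand, that median counts against less decay. A rise needed a higher median as well as a low fry p, so fry alone (direction up, fry adjusted p = 0.0546) did not meet it. The third quartile of 0.18 lay above 0.1, which was weighed only after the values were seen. Less decay stays open because of this spread among the 8 genes and the fry result. Neither was part of the bound set beforehand for no loss of decay.

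Of the tests on footprints in genes with little RNA, the ratio between knockdown libraries was planned before its result was seen, and the tests on gene span and on genes without listed RNA were chosen after, the latter with its values known. The 1146 genes not listed in the RNA-seq table had a median log2 ratio of knockdown to control of 1.82 (interquartile range 0.61 to 3.14), but all of them are among the 1288 genes with at most 0.1 RNA CPM in which the pattern was seen, so this restates it and more translation of RNA that these cells hold stays open. The counts ranked with gene span in the knockdown libraries (Spearman rho = 0.488 and 0.246 across 11802 genes) and not in the controls (-0.016 and -0.105), as unspecific reads spread over whole genes would give. Among 942 genes called higher, the median count was 1.58 and 1.61 times the background expected from span in knockdown replicate 1 and 2. Over 10 times that background was reached by 17.1% and 14.5% of them, which even spread does not give. The expected background itself comes from genes with at most 0.1 RNA CPM, where the rise was seen, so a low ratio is partly built in. Whether both knockdown libraries hold the same second pool of sequences cannot be told apart from independent background. The log2 ratio between them had an interquartile range of 0.668 over 501 genes called higher, between the bounds set beforehand. It was 1.27 over 1626 other genes. The call itself favours genes whose 2 knockdown counts agree, so this difference in spread says nothing for a shared pool. A biological difference in the knockdown cells stays untested.

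The concentration of Ribo-seq counts was examined only after it was seen. Of the 20 genes with most counts, 12 hold a snoRNA, miRNA or tRNA gene, against 10.2% of all genes, and RPS2, SEC14L1 and RPL27A among them (chosen by their counts) took 11.6, 14.4 and 10.8% of control replicate 1. Fragments of small RNAs encoded in introns could account for these. Across 1190 such genes the count per RNA count in the controls was 1.41 times that of genes with the same RNA level, too little to decide for the class. MAMLD1, which holds none and had 0.568 RNA CPM, took 9.08% of that library. RPL5 and DIPK1A, which overlap and share SNORD21 and SNORA66, had 10254 and 10266 counts there, although their RNA was at 739.9 and 18.3 CPM.

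For the fall of ribosomal protein RNAs, the scaling test was planned before its result was seen and the tests on other genes after, and the quartile comparison for abundant genes was added once the median of -0.103 had narrowly missed the bound of -0.1 first set. A loss of short or fragmented transcripts could give it, but respiratory chain and mitochondrial ribosomal protein genes, whose mRNAs are also short, had a median log2 fold change of 0.117 (interquartile range -0.016 to 0.254). Genes with the same RNA level had a median of -0.10 (-0.103, interquartile range -0.30 to 0.09), above that of the ribosomal protein genes (-0.51, interquartile range -0.65 to -0.33), so a general loss of abundant transcripts could give part of the fall but not all of it. Under size factors the number called lower was 63, as under TMM (100%), though these scalings differ little. A response of the cells to loss of RPS29 remains a hypothesis, and off-target effects of the hairpin, which bear on every knockdown difference, were not tested.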
